A study of Caenorhabditis elegans with 6 samples.

How the data were processed

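RNA-seq counts of 6 libraries of whole Caenorhabditis elegans at the fourth larval stage (L4) were analysed. Of these, 3 came from strain VC295, which carries the unc-30(ok613) allele on chromosome IV, and 3 from the wild-type strain N2. unc-30 encodes a homeodomain transcription factor that specifies GABAergic D-type motor neurons. Per the labels' protocols, about 40 gravid animals laid eggs for 3 hours on each 10 cm plate seeded with E. coli OP50, and the offspring grew to L4 at 20 °C. Total RNA was extracted from washed, frozen animals, and residual genomic DNA was digested with DNase, per the labels' protocols. Groups were taken from the strain label and replicate numbers from the sample titles. The genotype label names unc-30(ok613) for all 6 samples, including those whose strain and title are wild type, so it was not used. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

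The deposited files hold raw counts of reads per WormBase gene identifier, 1 file per library, made with HTSeq per the submitters' processing notes, which also name DESeq2. The aligner, the genome build, the annotation, the strand setting and all versions are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical copies such as histone and major sperm protein genes, can therefore not be separated with certainty. Each file has 46911 genes and no summary row. Identifiers were matched to Ensembl release 115 of WBcel235: 46863 were found there and 44059 had a symbol. Coordinates are from that annotation, 1-based. Genes with a count of 0 in every library numbered 25068.

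Total counts ran from 17318736 (wild type replicate 2) to 26377332 (wild type replicate 1), so that 3 counts, the floor used here, correspond to 0.114 to 0.173 CPM (counts scaled to a common library total). Ribosomal RNA genes took 0.394% of counts in wild type replicate 2 and 3.84% to 12.7% in the other 5 libraries. Mitochondrial genes other than rRNA took 1.72% to 2.43% in the mutant and 0.862% to 1.28% in wild type, so this share moved with the genotype. Each pair of replicates differed by far more than sampling noise (chi-square per degree of freedom 34.6 to 272 over genes), and none was treated as a repeated deposit. Intervals and floors cover counting error only. Folds of genes with few counts in a group are imprecise, and an exact interval is given only where a group had 3 counts or fewer.

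Differential expression was tested with the quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3), with trimmed mean of M-values (TMM) factors, the default expression filter, a robust fit, group as the only term and Benjamini-Hochberg adjusted p under 0.05 as the threshold. All adjusted p-values of single genes in the text come from this test unless another is named. The filter kept 14506 genes. Log2 fold changes are mutant minus wild type, with standard errors from the fit, and levels are TMM-scaled CPM given as mean ± SD over 3 libraries. TMM factors were 0.654 to 0.760 in the mutant and 1.38 to 1.49 in wild type. Scaling by total counts alone therefore lowers the median log2 fold change of all genes by 1.01, and every direction reported is relative to the TMM reference. The statement of a change at least 2-fold uses the fitted value, not a test against a 2-fold change.

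The 32 gene lists, the main test and the rule for naming genes were fixed before the data were examined. Lists were compiled from general knowledge of the pathways, or by gene family name. A total of 6 listed symbols had no match. Lists were tested with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, two-sided, adjusted over the 32 lists. An estimated correlation and fry were alternatives. The rule named unc-30, the 8 genes with the largest rise and the 8 with the largest fall among genes past the threshold, with a mean of at least 5 CPM in the higher group and no overlap between groups, and for each list up to 4 examples. These were the 2 largest rises and the 2 largest falls among members past the threshold, or, where none passed, the member with the highest CPM.

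The fits were tested on simulated counts for this comparison, drawn from the means, dispersions and library sizes of 14114 to 14167 genes, with 200 genes changed. A first draw gave 13 false calls among 82. This exceeded the limit of 15% set for the test, so 6 more draws were added and a limit of 12% for the pooled share was set after that result was seen, and all 7 draws were pooled. Of the calls, 7.82% were false (4.49% to 15.9% per draw), 71.9% of 4-fold and 5.57% of 2-fold changes were recovered, and no called gene had the wrong sign. DESeq2 had 26.6% false calls and limma-voom 8.67% on the same draws. At an unadjusted camera p under 0.05, a list of 25 genes moved by 2-fold was called in 7 of 7 draws, and an unmoved list of the same size in 0. The simulated genes vary independently, so the draws do not test how camera behaves where genes of a list vary together. Each draw changed only 200 genes, as many up as down, at library sizes that included the fitted TMM factors. The real fit called 5511 of 14506 genes. The draws do not test signs, false calls or recovery in that setting, or where the scaling is in doubt.

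Alternatives set before the data were examined were relative-log-expression and upper-quartile factors, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, and each library left out. Added after seeing the data were scaling by total counts, removal of rRNA genes, removal of each library's trend with gene length, and a germline score (mean log2 CPM of the germline list) as a covariate. Principal components used log2 CPM with a prior count of 2. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.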

Results

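The series profiled RNA of whole L4 animals of the unc-30(ok613) strain and of wild-type N2, with 3 libraries in each group. Total counts were 20188810 to 24498576 in the mutant and 17318736 to 26377332 in wild type. Genes with at least 1 count numbered 17088 to 17525 in the mutant and 18373 to 19477 in wild type. The design asks which genes differ between the genotypes at this stage.

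The mutated gene itself did not pass the test between the genotypes. Counts of unc-30 (WBGene00006766, chromosome IV, 13118977 to 13124406, plus strand, WBcel235) were 20, 24 and 17 in mutant replicates 1 to 3, and 23, 26 and 17 in wild type. These correspond to 1.33 ± 0.0671 CPM in the mutant and 0.729 ± 0.296 CPM in wild type (SD, n = 3 each), a log2 fold change of 0.88 ± 0.42 (SE; edgeR adjusted p = 0.128) that becomes -0.13 with scaling by total counts. On the TMM scale each mutant value lay above each wild-type value. Reads were counted over the whole gene and the extent of the deletion is not given in the sources used here, so these counts do not check the labels.

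Listed genes of the GABAergic motor neurons that passed the test moved in both directions, but the 2 D-type rises were those of neuropeptide genes. unc-25, which encodes the GABA-synthesising glutamate decarboxylase (chromosome III, 12942651 to 12949883), was 2.88-fold lower in the mutant, at 4.90 ± 1.18 CPM against 14.1 ± 2.44 CPM (SD, n = 3; edgeR adjusted p = 0.00632), and each mutant value lay below each wild-type value. ttr-39, a transthyretin-like gene of D-type neurons (chromosome IV, 10088367 to 10089877), had 2 counts over the mutant libraries and 151 over wild type. The scaled ratio of wild type to mutant was 36.3 (exact 95% interval 9.87 to 302), and the edgeR adjusted p was 0.00281. The neuropeptide genes flp-11 and flp-13, also on the D-type list, rose by 5.22-fold and 5.64-fold (edgeR adjusted p = 0.00186 and 0.00194). Their rise is not particular to D-type genes, since 29 of 30 tested FMRFamide-like peptide genes rose.

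Of 13 tested genes of GABA synthesis, transport and reception, 2 rose, 1 fell and 10 did not pass (1 rose and 1 fell when adjusted over the list alone). The rises were lgc-38, a ligand-gated channel subunit (log2 fold change 1.17), and gta-1, the GABA transaminase (1.04); neither passed with scaling by total counts, where their log2 fold changes were 0.14 and 0.02, and lgc-38 lost its call when any library but mutant replicate 1 was left out. Among the 10 that did not pass, unc-47 and unc-46 had log2 fold changes of -1.12 and -0.79 (edgeR adjusted p = 0.113 and 0.233). Both passed as lower with scaling by total counts (edgeR adjusted p = 0.00768 and 0.0103). snf-11, also among the 10, had a log2 fold change of 0.91 (edgeR adjusted p = 0.0701), and -0.11 with scaling by total counts. Of 9 tested D-type genes, 2 rose, 2 fell and 5 did not pass, and the same numbers held when adjusted over the list alone. Neither list was called by camera (adjusted p = 0.633 and 0.628), and their medians of 0.23 and 0.02 became -0.78 and -0.98 with scaling by total counts, with 0 rises and 6 falls for the first and 2 and 5 for the second.

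**Figure D1:**
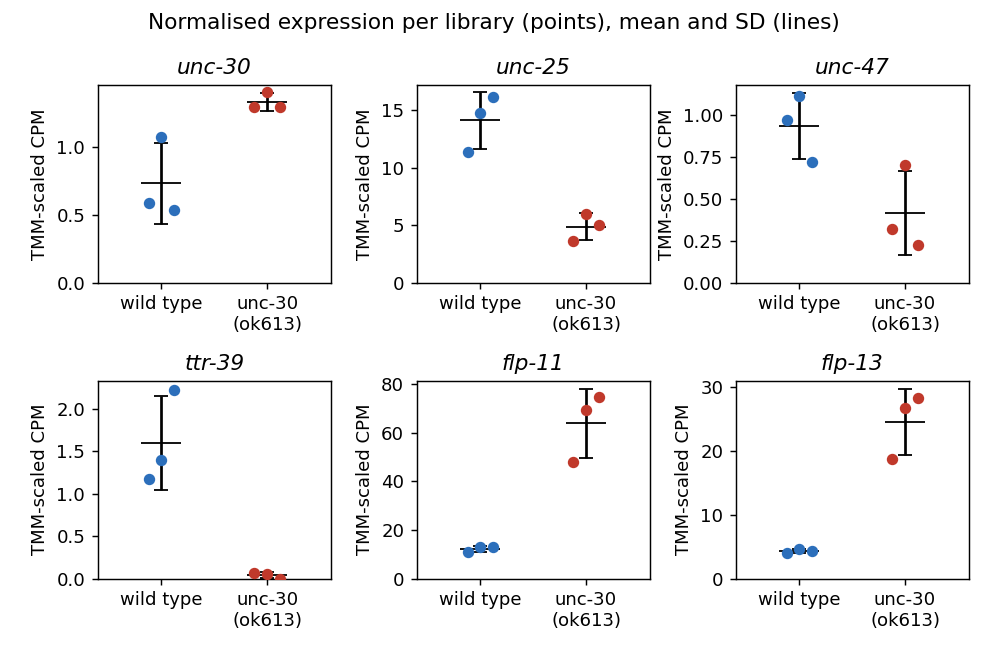
TMM-scaled CPM (vertical axis) of unc-30 and 5 genes of GABAergic motor neurons in each library (points), with the mean (wide line) and SD (bars) of 3 libraries per genotype. unc-25 lies at 14.1 CPM in wild type and 4.90 CPM in the mutant, while flp-13 lies at 4.36 and 24.6 CPM, and unc-47 (edgeR test not passed) and unc-30 are near 1 CPM.

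Across all 14506 tested genes, 5511 differed between the genotypes, 2476 higher and 3035 lower in the mutant. At least 2-fold changes numbered 4476, of which 1746 were higher and 2730 lower. The values of the groups did not overlap for 7635 genes (52.6%), where chance gives 10%. With scaling by total counts the count was 8673, of which 498 were higher and 8175 lower, so the share of higher calls was 5.74% in place of 44.9%. The count also depended on single libraries: it was 2826 without mutant replicate 2, 2791 without mutant replicate 3 and 3466 without wild type replicate 3.

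The first principal component held 73.2% of the variance and separated the genotypes. Mutant replicate 1 lay at -31.8 on it and mutant replicates 2 and 3 at -93.3 and -94.7, while wild type replicate 2 lay at 36.0 and the other wild-type libraries at 90.3 and 93.5. Correlations of log2 CPM across genes were 0.954 to 0.985 within the mutant, 0.936 to 0.958 within wild type and 0.826 to 0.938 between them.

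**Figure D2:**
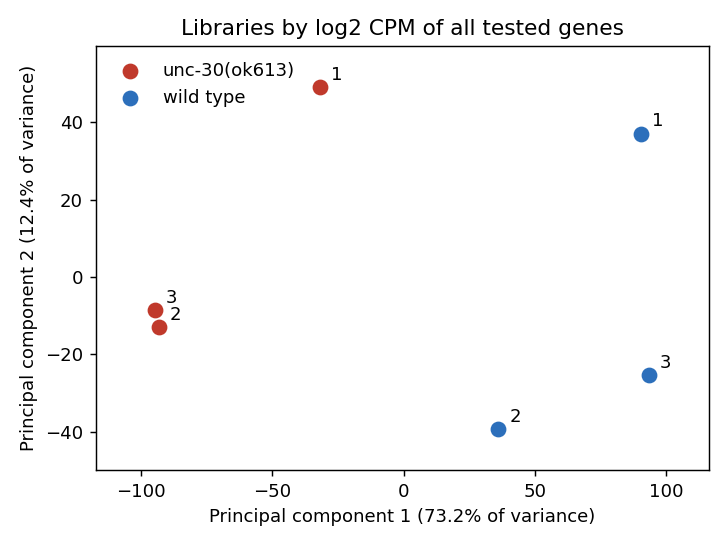
The 6 libraries on the first (horizontal) and second (vertical) principal components of log2 CPM, with replicate numbers beside the points; the components hold 73.2% and 12.4% of the variance. Mutant replicate 1 (-31.8) and wild type replicate 2 (36.0) lie nearer to the other genotype on the first component than the remaining libraries of their groups.

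Among the strongest rises, gmd-2, a GDP-mannose dehydratase gene (chromosome I, 12292202 to 12293936), went from 0.433 ± 0.431 CPM to 49.5 ± 32.3 CPM (SD, n = 3; log2 fold change 6.76 ± 1.01, SE). The cuticle collagen gene col-176 (chromosome X, 10077597 to 10078728) rose 40.9-fold. The other 6 were K06H6.1, C14C6.8, K06H6.2, C14C6.3, C14C6.6 and F14F8.8, with log2 fold changes of 4.79 to 6.02. These 6 had 11 to 117 counts over the wild-type libraries, so the folds are imprecise. The sizes of these rises depend on wild type replicate 1: without it gmd-2 had a log2 fold change of 8.04 and the 6 others 6.57 to 8.42. The naming rule asked for a mean of at least 5 CPM in the higher group, which left out ttr-39. Under that rule the 8 largest falls were ZK354.3 (chromosome IV, 5310042 to 5311445), W09C3.2, ZK354.7, the C-type lectin gene clec-223, T05D4.5, C17F3.3, Y106G6D.3 and H27M09.5. ZK354.3 fell from 15.5 ± 11.3 CPM to 0.343 ± 0.428 CPM, 43.9-fold (SD, n = 3), and the falls of the other 7 were 22.9-fold to 32.1-fold. These 8 genes had 11 to 26 counts over the mutant libraries, so the folds are imprecise. Adjusted p-values of these 16 genes (edgeR) were 0.00204 to 0.0339; clec-223 was no longer called with length trends removed (adjusted p = 0.0514). Its fall rested largely on wild type replicate 1 (17.4 CPM, against 0.781 and 2.60 CPM in replicates 2 and 3): without that library the log2 fold change went from -4.83 to -2.80 (edgeR adjusted p = 0.0499), and its call was lost without mutant replicate 2 (0.115) or 3 (0.107). Without mutant replicate 1, ZK354.3, W09C3.2, ZK354.7, clec-223 and C17F3.3 had log2 fold changes of -6.13 to -7.40; without mutant replicate 3 those of ZK354.7 and H27M09.5 were -4.32 and -3.92. C17F3.3 lost its call without mutant replicate 2 or 3 or wild type replicate 1 or 3 (adjusted p = 0.0544 to 0.0718). With no expression filter K06H6.2, C14C6.6, clec-223 and C17F3.3 were not called.

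Most FMRFamide-like peptide genes rose. Of 30 tested FMRFamide-like peptide genes, 29 rose, 0 fell and 1 did not pass, and the same numbers held when adjusted over the list alone. The list's median log2 fold change was 2.03 under TMM and 1.01 with scaling by total counts, where 24 members rose. The largest rises were those of flp-26 (6.24-fold, 2.69 ± 0.461 to 16.8 ± 3.64 CPM) and flp-20 (5.74-fold). Of 22 insulin-like peptide genes, 12 rose, 0 fell and 10 did not pass (13 and 0 adjusted over the list alone), led by ins-35 (9.67-fold) and ins-27 (6.14-fold); with scaling by total counts 5 rose and 2 fell, and the median of 1.46 became 0.44. The camera adjusted p was 3.81e-27 for FMRFamide-like peptides and 2.97e-06 for insulin-like peptides, and for each the adjusted p = 0.451 with an estimated correlation. Of the 32 lists, camera called 17 at its preset correlation and 0 with an estimated correlation, and 4 of the 10 splits of the 6 samples into 3 and 3, the real split included, called at least as many.

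Other lists that hold neuronal genes were mixed under TMM, and falls outnumbered rises with scaling by total counts. Of 15 tested genes of cholinergic neurons and acetylcholine receptors, 4 rose, 1 fell and 10 did not pass, with the same numbers adjusted over the list alone. unc-17, the vesicular acetylcholine transporter gene, rose 3.00-fold and cho-1, the choline transporter gene, 2.12-fold, whereas ace-1, an acetylcholinesterase gene, fell 4.08-fold; the rises of unc-17 and cho-1 did not pass with scaling by total counts, and that of cho-1 was lost without any of 4 single libraries. Of 20 pan-neuronal genes, 4 rose, 4 fell and 12 did not pass, again with the same numbers adjusted over the list alone. egl-21 and egl-3, which encode enzymes that process neuropeptide precursors, rose 4.58-fold and 3.36-fold, and maco-1 and unc-104 (a kinesin of synaptic vesicle transport) fell 3.45-fold and 3.35-fold. Neither list was called (camera adjusted p = 0.439 and 0.742). The cholinergic median of 0.39 became -0.62 with scaling by total counts (0 rises, 7 falls) and the pan-neuronal median of -0.41 became -1.44 (3 rises, 14 falls); with length trends removed the latter was 0.08. Of 28 tested chemoreceptor genes, 4 rose, 3 fell and 21 did not pass, with the same numbers adjusted over the list alone (camera adjusted p = 0.445); with scaling by total counts 2 rose and 10 fell. srd-23 and srw-85 rose 8.61-fold and 7.27-fold, and srj-14 and srh-70 fell 4.10-fold and 3.80-fold. In wild type replicates 1 to 3 srd-23 had only 7, 4 and 0 counts. The calls of maco-1 and srh-70 were lost without mutant replicate 2 or 3, and that of srh-70 also without wild type replicate 3.

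Camera called 3 families of secreted immune effectors towards higher expression in the mutant, relative to the TMM reference. Of 101 tested C-type lectin genes, 37 rose, 10 fell and 54 did not pass (39 and 12 adjusted over the list alone); clec-61 and clec-70 rose 10.1-fold and 9.70-fold, and clec-223 (mostly through wild type replicate 1) and clec-142 fell 28.4-fold and 20.1-fold. Of 12 lysozyme genes, 8 rose and 0 fell, also adjusted over the list alone, with ilys-3 at 5.36-fold and lys-7 at 3.84-fold. Of 22 saposin-like genes, 16 rose and 1 fell, also adjusted over the list alone. Among them spp-12 and spp-13 rose 10.6-fold and 5.37-fold and spp-24 fell 3.02-fold. Random lists matched on exonic length and mean expression had median log2 fold changes of 0.67 for lysozymes, 0.62 for saposin-like genes and -0.09 for lectins. The medians of the lists themselves were 1.32, 1.33 and 0.82. Some of these folds rest on few reads. In wild type replicates 1 to 3 spp-12 had 3, 2 and 6 counts and clec-70 had 3, 10 and 8. In mutant replicates 1 to 3 clec-142 had 2, 4 and 0 counts. The camera adjusted p was 0.000360 for lectins, 0.000360 for lysozymes and 2.50e-06 for saposin-like genes, and for each the adjusted p = 0.451 with an estimated correlation. With scaling by total counts the lysozyme and saposin-like medians were 0.31 each, with 1 rise and 1 fall for lysozymes and 3 rises and 2 falls for saposin-like genes, and the lectin median turned from 0.82 to -0.20, with 9 rises and 26 falls; lys-7 and spp-13 no longer passed there, nor did spp-13 with length trends removed. Leaving out single libraries ended the calls of lys-7 (2 libraries), spp-13 (4) and spp-24 (5), and moved clec-61 to 3.98 and spp-13 to 3.56 without wild type replicate 2 and clec-142 to -5.11 without mutant replicate 2 (log2 fold changes).

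Of 17 genes of the intracellular pathogen response, 0 rose, 5 fell and 12 did not pass, with the same numbers adjusted over the list alone (median -0.95; camera adjusted p = 0.0236, and adjusted p = 0.451 with an estimated correlation). pals-23 fell 4.82-fold, and pals-4 had 2 counts in the mutant against 58 in wild type (scaled ratio 13.9, exact 95% interval 3.69 to 118). Its log2 fold change of -3.66 became -6.93 without mutant replicate 1, and its call was lost without mutant replicate 2 (-2.99, edgeR adjusted p = 0.0741) or 3 or wild type replicate 3. The camera call of this list was lost without mutant replicate 1 (adjusted p = 0.0670) and with scaling by total counts (0.0539), where 16 members fell. Of 10 genes dependent on the p38 kinase PMK-1, 2 rose, irg-4 (2.31-fold) and clec-67 (2.06-fold), and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.0522). With scaling by total counts neither rise passed, 1 member fell and the median turned from 0.99 to -0.03, while camera called the list there relative to other genes (adjusted p = 0.0181). That call used the preset correlation, and camera with an estimated correlation gave the list adjusted p = 0.668 under TMM. Of 15 epidermal antimicrobial peptide genes, cnc-3 rose 7.53-fold, nlp-25 fell 3.38-fold and 13 did not pass (0 and 0 adjusted over the list alone; camera adjusted p = 0.422); cnc-3 did not pass with scaling by total counts, where 3 members fell, or with length trends removed. The calls of irg-4 and cnc-3 were each lost without any of 4 single libraries, of nlp-25 without any of 3 and of clec-67 without either of 2, and without wild type replicate 2 cnc-3 had a log2 fold change of 4.37.

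Longevity and detoxification genes rose in part. Of 20 tested DAF-16 activated targets, 10 rose, 1 fell and 9 did not pass, also adjusted over the list alone. asah-1 (acid ceramidase) rose 4.70-fold, dod-6 rose 4.25-fold and the linker histone gene hil-1 fell 3.12-fold. Of 16 SKN-1 targets, 7 rose and 0 fell (8 and 0 adjusted over the list alone), led by gst-10 (3.40-fold) and the peroxiredoxin gene prdx-2 (2.67-fold). Among the 9 that did not pass, gst-4 and gcs-1 had log2 fold changes of -0.48 and -0.45, and both fell with scaling by total counts. Of 36 glutathione S-transferase genes, 16 rose and 0 fell (18 and 0 adjusted over the list alone), led by gst-20 (5.66-fold) and gst-27 (4.64-fold). The gst genes of the SKN-1 list are also on this list, so the results of these lists are not separate. Camera called these lists (adjusted p = 0.000141, 0.00977 and 6.50e-06), and for each the adjusted p = 0.451 with an estimated correlation. With scaling by total counts the DAF-16 median was 0.12, and the SKN-1 and glutathione S-transferase medians turned to -0.03 and -0.29, and prdx-2 no longer passed; the numbers of rises and falls there were 3 and 3, 1 and 3, and 6 and 3. The fall of hil-1 lost its call without any of 4 single libraries.

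The same camera test called none of the remaining lists of stress and detoxification genes, but the heat shock list was called in 5 alternatives (adjusted p = 0.0135 to 0.0493) and the endoplasmic reticulum list in 2 (0.0337 and 0.0449). Of 10 DAF-16 repressed targets, dao-2 rose 10.6-fold and 9 did not pass, also adjusted over the list alone (camera adjusted p = 0.586). Of 48 cytochrome P450 genes, 3 rose and 6 fell (0 and 2 adjusted over the list alone; camera adjusted p = 0.633), with cyp-13B1 and cyp-23A1 3.44-fold and 3.03-fold higher, cyp-25A3 4.70-fold lower and cyp-33C3 lower at 0.709 CPM against 2.86 CPM. Of 55 UDP-glucuronosyltransferase genes, 3 rose and 12 fell (1 and 10 adjusted over the list alone; camera adjusted p = 0.340), with ugt-57 and ugt-65 at 6.08-fold and 2.95-fold higher and ugt-54 and ugt-41 at 4.37-fold and 3.80-fold lower. Of 8 heat shock genes, hsp-1 (2.49-fold) and hsp-90 (2.27-fold) rose and 6 did not pass, also adjusted over the list alone (camera adjusted p = 0.0922). Of 10 genes of the mitochondrial unfolded protein response, 3 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.445): gpd-2 and timm-23 were 3.30-fold and 2.89-fold higher, and dnj-10 and the protease gene lonp-1 3.02-fold and 2.59-fold lower. Of 16 genes of the endoplasmic reticulum response, 8 rose and 2 fell (8 and 4 adjusted over the list alone; camera adjusted p = 0.167). pdi-2 and dnj-27 rose 4.88-fold and 3.51-fold, and the stress sensors ire-1 and pek-1 fell 2.69-fold and 2.46-fold. With scaling by total counts the rises of cyp-13B1, cyp-23A1, ugt-57, ugt-65, hsp-1, hsp-90, pdi-2 and dnj-27 did not pass. The numbers of rises and falls there were 1 and 8 for the endoplasmic reticulum response (median 0.56 under TMM, -0.46 there), 2 and 6 for the mitochondrial response, 0 and 2 for heat shock genes, 0 and 28 for cytochrome P450 genes, 0 and 37 for UDP-glucuronosyltransferases, and 1 and 2 for DAF-16 repressed targets. Mutant replicates 2 and 3 were each needed for the calls of cyp-13B1, cyp-23A1, ugt-54, ugt-57, ugt-65, dao-2, pdi-2 and pek-1. Wild type replicate 1 was also needed for those of cyp-23A1, ugt-57, ugt-65, dao-2 and pdi-2. The calls of cyp-23A1, ugt-65 and pdi-2 needed wild type replicate 3 as well. The log2 fold changes of dao-2 and pdi-2 were 4.62 and 3.11 without wild type replicate 2, and that of ugt-54 was -1.44 without wild type replicate 3.

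Of 80 tested cytosolic ribosomal protein genes, 79 rose and 1 fell, also adjusted over the list alone. rpl-11.2 and rpl-37 rose by 2.46 and 2.35 on the log2 scale, and rpl-42 fell by 1.69. The median log2 fold change was 1.84 under TMM and 0.83 with scaling by total counts, where 69 rose and 1 fell. Of 37 histone genes, 16 rose and 1 fell (17 and 1 adjusted over the list alone), with his-17 6.28-fold and the linker histone gene his-24 3.91-fold higher and his-63 4.46-fold lower; with scaling by total counts the median of 1.13 became 0.11, with 0 rises and 2 falls, so that neither his-17 nor his-24 passed; his-17 did not pass with length trends removed either. Without wild type replicate 2 these 2 had log2 fold changes of 4.06 and 2.58, and the calls of his-17 and rpl-42 were lost without any of 4 and either of 2 single libraries. Camera called both lists (adjusted p = 6.72e-40 and 1.57e-05), and for each the adjusted p = 0.451 with an estimated correlation.

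Camera also called the muscle, intestine and fatty acid lists towards higher expression, though many intestine and fatty acid genes did not pass singly. Of 20 body wall muscle genes, 16 rose, 2 fell and 2 did not pass, also adjusted over the list alone: dim-1 and cpn-3 rose 3.19-fold and 3.16-fold, and ttn-1 and unc-22, which encode giant muscle proteins, fell 2.66-fold and 1.89-fold. With length trends removed, ttn-1 and unc-22 no longer passed (log2 fold changes -0.21 and 0.04). Of 15 intestine markers, 6 rose, 0 fell and 9 did not pass, also adjusted over the list alone, led by the protease genes cpr-1 (6.15-fold) and asp-1 (3.89-fold). Of 16 fatty acid synthesis genes, 7 rose, 0 fell and 9 did not pass, also adjusted over the list alone, led by let-767 (2.67-fold) and fat-5 (2.64-fold). The camera adjusted p-values were 4.78e-05, 0.0199 and 0.00303; with an estimated correlation they were adjusted p = 0.462, 0.554 and 0.619. With scaling by total counts the muscle median was 0.23 (2 rises, 4 falls), the intestine list lost its camera call (adjusted p = 0.0539; median -0.35, 2 rises, 5 falls) and the fatty acid median turned to -0.24 (0 rises, 3 falls), and let-767 and fat-5 no longer passed. The calls of fat-5, ttn-1 and unc-22 were lost without any of 2, 4 and 5 single libraries.

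Some genes tied to the larval stage moved with the genotype. Of 135 cuticle collagen genes, 36 rose, 2 fell and 97 did not pass (28 and 1 adjusted over the list alone), with col-176 and col-41 (16.9-fold) at the top and col-135 and col-152 12.7-fold and 4.15-fold lower. Of 71 molting cycle and hedgehog-related genes, 11 rose and 3 fell (2 and 2 adjusted over the list alone): noah-2 and wrt-10 rose 9.87-fold and 9.57-fold, and ptr-3 and grd-6 fell 4.16-fold and 3.61-fold. Of 74 sperm genes, 0 rose, 18 fell and 56 did not pass (0 and 12 adjusted over the list alone), and spe-11 and spe-12 fell by 3.75 and 3.47 on the log2 scale. Camera called the 3 lists (adjusted p = 3.92e-07, 0.000640 and 0.0102); with an estimated correlation they were adjusted p = 0.462, 0.668 and 0.787. The sperm call was lost without wild type replicate 3 (adjusted p = 0.141), and with scaling by total counts the molting median turned from 0.80 to -0.21, with 3 rises and 15 falls, and the collagen median of 1.20 became 0.21, with 13 rises and 8 falls; of the sperm genes 0 rose and 51 fell there (median -1.38). The falls of col-135 and grd-6 did not pass with length trends removed. Leaving out single libraries ended the calls of col-135 and col-152 (4 libraries each), noah-2 and wrt-10 (3 each), ptr-3 (1) and grd-6 (5). The log2 fold change of col-135 was -2.44 without wild type replicate 1 (edgeR adjusted p = 0.0845) and -5.48 without mutant replicate 1, those of noah-2 and wrt-10 were 4.69 and 4.17 without wild type replicate 2, and that of spe-12 was -2.81 without wild type replicate 3.

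Of 29 germline and oocyte genes, 0 rose and 4 fell (0 and 2 adjusted over the list alone; camera adjusted p = 0.445; with scaling by total counts 0 and 10). syp-1, a synaptonemal complex gene, fell 5.26-fold and the helicase gene glh-2 fell 2.67-fold, a call lost without mutant replicate 3. None of the 6 vitellogenin (yolk protein) genes passed in edgeR, also adjusted over the list alone (median -2.20; camera adjusted p = 0.116); with scaling by total counts 1 fell. With the germline score as a covariate vit-6 passed (log2 fold change -1.96, edgeR adjusted p = 0.0110) and camera called the list (adjusted p = 9.57e-05). Camera also called the list without mutant replicate 1 (adjusted p = 6.54e-05). These calls used the preset correlation, and camera with an estimated correlation gave the list adjusted p = 0.740 in the main fit. The most abundant, vit-6, had 4354 CPM in mutant replicate 1, 233 and 319 CPM in mutant replicates 2 and 3, and 9114, 2562 and 5097 CPM in wild type replicates 1 to 3.

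**Figure D3:**
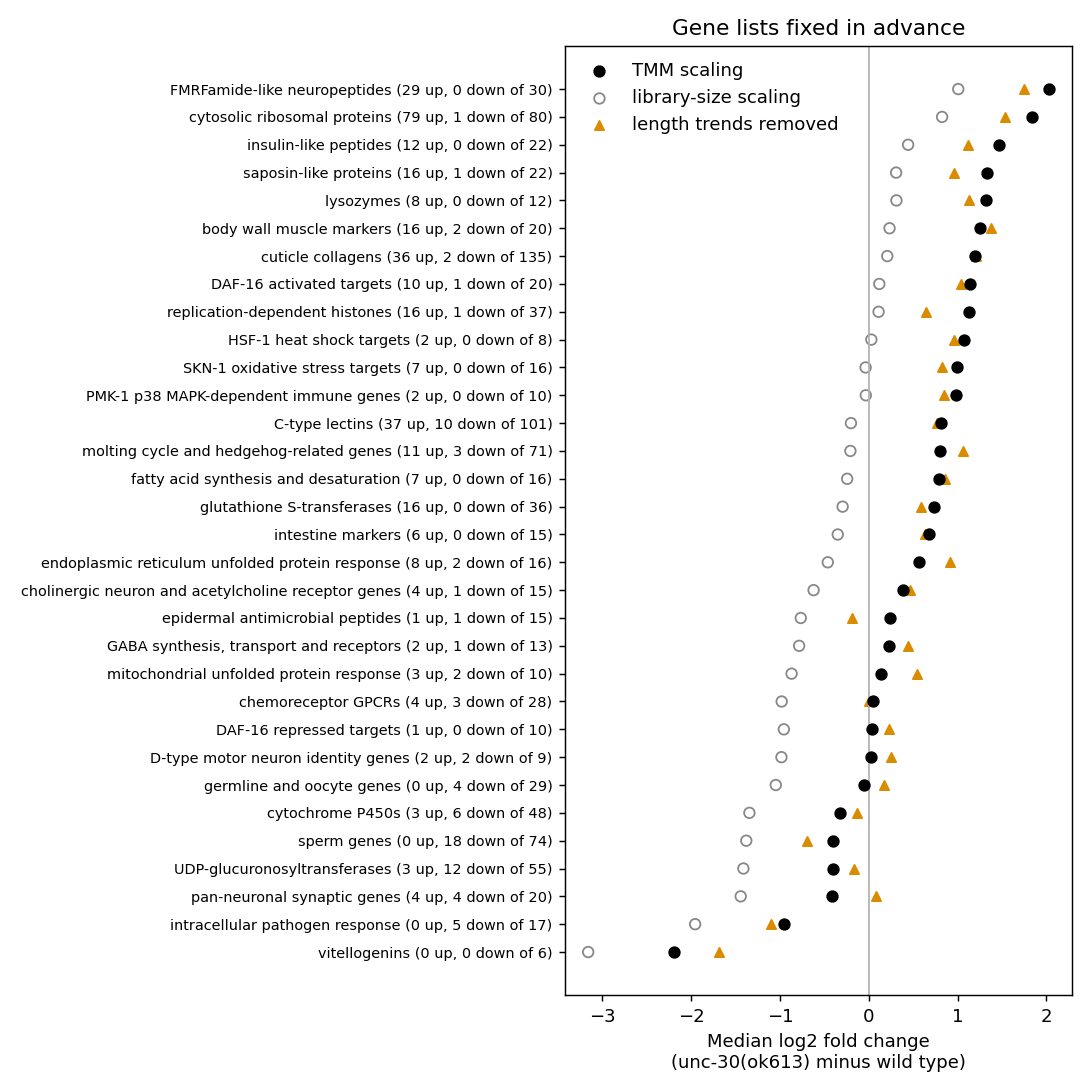
Median log2 fold change (horizontal axis, mutant minus wild type) of each of the 32 gene lists under TMM scaling (filled circles), scaling by total counts (open circles) and with length trends removed (triangles), with the numbers of members past the test beside each name. Scaling by total counts moves every list to the left by about the shift of all genes (1.01); FMRFamide-like peptides (1.01) and ribosomal proteins (0.83) stay above 0, and the lectin (-0.20), glutathione S-transferase (-0.29) and intestine (-0.35) medians fall below it.

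Fold changes also varied with gene length. Among 13958 protein-coding genes the median log2 fold change went from 0.48 in the shortest of 10 equal groups by length (median exonic length 442.5 bp) to -0.60 in the longest (4064.5 bp). Spearman's rho with length was -0.232 across genes, which are not independent replicates. Between single libraries of the same genotype the sign of rho depends on the order of subtraction, and its size was 0.0242 to 0.298. The largest, 0.298 and 0.259 between wild-type libraries, exceeded the size between genotypes.

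**Figure D4:**
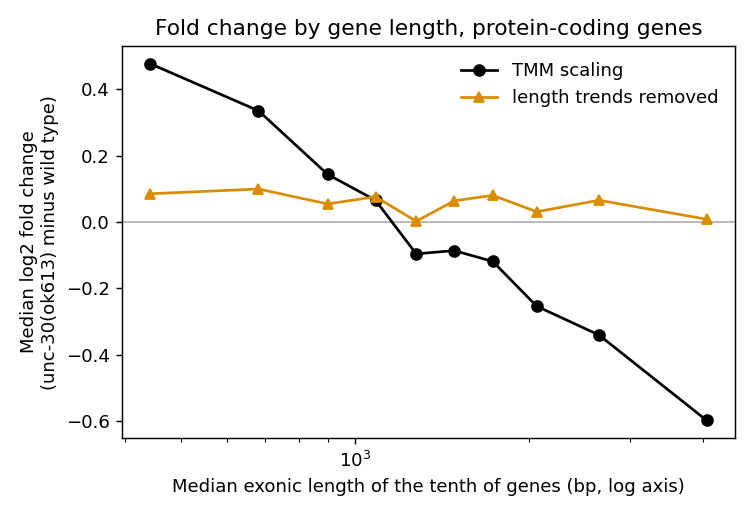
Median log2 fold change (vertical axis, mutant minus wild type) of protein-coding genes in 10 groups of exonic length (horizontal log axis, bp), under TMM scaling (circles) and with each library's length trend removed (triangles). It goes from 0.48 to -0.60 under TMM, and from 0.08 to 0.01 with the trends removed.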

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

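Tests with scaling by total counts, without rRNA genes, with length trends removed and with the germline covariate were chosen only after the result was seen. The counts of genes changed, higher and lower stayed within 1.5 times under the other scalings, filters and tools, from 5333 genes without a filter to 6109 with DESeq2 (16 adjusted p-values were NA). Scaling by total counts gave 8673 changed genes, 498 higher and 8175 lower, and 7459 changed at least 2-fold; of the 5511 calls, 3533 were called in the same direction. Leaving out 1 library gave 2791 to 6154 changed genes (1359 to 2897 higher, 1424 to 3257 lower, 2700 to 5419 at least 2-fold). The counts fell by over 1.5 times without mutant replicate 2 (2826) or 3 (2791) or wild type replicate 3 (3466), except the count at least 2-fold without the last (3199); the cause was not tested. With the replicate number as a block, 6943 genes were called, 3230 higher and 3713 lower, 5052 of them at least 2-fold. The samples were not paired in the main test, since nothing in the labels says that a number marks a shared day. The deviations of same-numbered samples correlated at 0.46, 0.44 and -0.07 across genes. Mutant replicates 1 and 2 correlated best with their own number and mutant replicate 3 did not, so a factor shared by number stays open.

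Camera called 17 lists, but 0 with an estimated correlation. The adjusted p was then 0.451 for FMRFamide-like peptides, insulin-like peptides, C-type lectins, lysozymes, saposin-like genes, the intracellular pathogen response, DAF-16 activated targets, SKN-1 targets, glutathione S-transferases, histones and ribosomal proteins. It was 0.462 for muscle and collagens, 0.554 for intestine, 0.619 for fatty acid synthesis, 0.668 for molting genes and 0.787 for sperm genes. With fry, which asks whether a list's genes move on balance in a single direction, 14 were called, and collagens (0.0504), molting genes (0.169) and sperm genes (0.217) were not. The pathogen response lost its call with the 1 CPM filter (0.109) and with scaling by total counts (0.0539), as did intestine markers with the latter (0.0539); the cause was not tested. Leaving out 1 library gave adjusted p of 0.00926 to 0.0670 for the pathogen response and 0.000139 to 0.141 for sperm genes.

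Other lists gained a call. PMK-1 genes were called without a filter (0.0150), with limma-voom (0.0324), the replicate block (0.0154) and scaling by total counts (0.0181), and leaving out 1 library gave 0.0164 to 0.246. Heat shock genes were called without a filter (0.0203), with DESeq2 (0.0392), limma-voom (0.0458) and length trends removed (0.0493; 0.0135 to 0.212 with 1 library left out). Endoplasmic reticulum genes were called with length trends removed (0.0337; 0.0449 to 0.367 with 1 library left out). Vitellogenins were called with limma-voom (0.0215), the block (0.000988) and the germline covariate (9.57e-05; 6.54e-05 to 0.292 with 1 library left out). Lists that were not called turned direction with scaling by total counts (pan-neuronal 0.888, cytochrome P450 0.980, germline 0.931), length trends removed (epidermal peptides 0.761), the germline covariate (DAF-16 repressed 0.912, germline 0.744) and the 1 CPM filter (chemoreceptors 0.809). With 1 library left out, directions turned for DAF-16 repressed targets (0.336 to 0.833), cytochrome P450 (0.436 to 0.819), germline genes (0.00610 to 0.916, called without mutant replicate 1) and chemoreceptors (0.367 to 0.973). unc-30 turned to -0.13 with scaling by total counts and was not called under any setting (adjusted p 0.0531 to 0.789, log2 fold change 0.69 to 1.24 with 1 library left out; the 1 CPM filter removed it).

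Of 102 named genes that passed the test, 22 lost their call with scaling by total counts, 35 without mutant replicate 3, 31 without mutant replicate 2, 21 and 19 without wild type replicate 3 and 1, 15 without a filter, 10 with the germline covariate, 8 with length trends removed (unc-22 among them), 5 each with limma-voom and the block, and 4 or fewer under each other setting. unc-22 reversed to 0.038 with length trends removed (adjusted p = 0.912). Apart from unc-22 and unc-30, no named gene changed sign under any setting. Of the 102, 35 lost their call without at least 1 of the 6 libraries, 27 moved by over 1.5 times in fold without at least 1, and 50 did either.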

Other observations

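Tests of the length trend, the germline score, a swapped library and the other splits of gene counts were chosen only after the result was seen. So were the background values on the TMM scale and the test of evenly spread DNA, which replaced a share of genes that the expression filter had fixed at 100%.

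A stretch of chromosome V held 5 of the 8 genes named for the largest rise. Between 543469 and 589657 (46.2 kb, WBcel235), 19 genes are annotated and 8 were tested, and all 8 rose, with a median log2 fold change of 5.18 (4.11 with scaling by total counts); without wild type replicate 1 the 5 had log2 fold changes of 6.61 to 8.42. The stretch was chosen after its values were seen, and read sharing between its genes was not examined. Annotated pseudogenes leaned the other way: of 450 tested, 11 rose and 222 fell, with a median log2 fold change of -1.34, against -0.06 for 13958 protein-coding genes. Of genes within 2 Mb of unc-30, 222 of 588 were called, against 5289 of 13918 others (two-sided Fisher's exact p = 0.931, across genes, which are not independent).

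The number of genes that differ is the first pattern. Mutant replicate 1 differs from mutant replicates 2 and 3 along much the same axis as the genotypes do, with correlations of -0.680 to -0.479 across genes against mutant minus wild-type differences of other libraries, and wild type replicate 2 leans towards the mutant (0.217 to 0.569). A length trend as the whole cause is argued against by 4616 of 5511 calls that kept their direction with it removed. With the germline score as a covariate 5208 did so. This cannot decide on germline timing, since the score varied mainly within groups. It was 7.33, 5.76 and 5.81 in mutant replicates 1 to 3, and 7.34, 6.40 and 6.41 in wild type. Evenly spread DNA was set at the wild-type excess of chemoreceptor genes (0.0434 CPM per exonic kb, excesses as shares of total counts). It would supply 0.336% of the summed excess of the genes lower under TMM. For the genes lower with scaling by total counts it would supply 0.341%. A small share was bound to result, since the smallest excess among the genes lower under TMM was 0.199 CPM per kb. The test therefore shows only that background at the measured level is small beside these excesses. On the TMM scale chemoreceptor genes have no wild-type excess. Unspliced or uneven background cannot be told apart, since the direction turns with the scaling (chemoreceptor share of total counts 1.70 times higher in wild type, between the bounds set, but 0.839 times on the TMM scale, where 222 of 450 pseudogenes fell). Germline timing, molting phase, RNA composition and the mutation itself stay open. Genotype and strain coincide, so other differences between VC295 and N2, or in their growth or preparation, cannot be told apart from the mutation.

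The rise of neuropeptide genes is the second. The median of FMRFamide-like peptide genes, 2.03, lay at percentile 100 of 10000 random lists matched on exonic length and mean expression (matched median 0.38, 95% range -0.06 to 0.80), which argues against length and expression level as the whole cause. The insulin-like list lay at percentile 99.99, but ribosomal protein genes, lysozymes, saposin-like genes, lectins, PMK-1 genes and DAF-16 targets also lay at 97.87 to 100. Their matched medians were 1.26, 0.67, 0.62, -0.09, 0.16 and 0.44 in that order, and 0.13 for the insulin-like list. A larger share of nervous tissue RNA was not tested by itself. Of 20 pan-neuronal genes, 4 rose and 4 fell under TMM (median -0.41). With length trends removed 5 rose and 2 fell (median 0.08), so the tally depends in part on gene length. Stage differences, other differences between the strains and the mutation itself stay open, and no biological explanation was tested.

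The third is that unc-30 did not pass the test, although each mutant value lay above each wild-type value on the TMM scale. A swapped or mislabelled library is argued against by unc-25, whose lowest wild-type value was 1.90 times its highest mutant value, and ttr-39 had 0 or 1 count in each mutant library against 34 to 71 in wild type. Both were on lists fixed before the data were examined. Transcripts from the rest of the mutated gene are a possible explanation that gene-level counts cannot test.

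With 3 samples against 3 there are 10 splits, too few for a share under 0.05, and 1 of them, the real split, gave as many changed genes. The real split called 5511 genes in edgeR (4476 at least 2-fold, 2476 higher, 3035 lower) and the highest of the other splits 0 (1697 at an unadjusted p under 0.05, against 7084 for the real split; no other tool was run on the splits). For gene lists, 4 of the 10 splits called as many as the real 17, with up to 22 in another split. Each of the other splits keeps 2 libraries of a genotype together, so part of the genotype difference remains in it, and these counts do not show variation apart from genotype.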
